A study of Mus musculus with 15 samples.

How the data were processed

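Tumor RNA was profiled with the nCounter Mouse Immune Exhaustion Panel on an nCounter MAX system, per the labels. Frozen tumors were kept until their radioactivity had decayed to background, homogenized in TRIzol, and the RNA was purified on columns, also per the labels. The deposited table gives log2 normalized counts for 625 genes in 15 samples, with values from -0.64 to 14.70 and 0 control probes. The software, the normalization genes, the background handling and any filter that the authors used are not given in the sources used here. In each sample, 2 to the power of the value was a whole multiple of a single step, within 4.6e-05 of a count, so each sample had been multiplied by 1 factor and the counts could be recovered. The step, the normalized value of 1 count, ran from 0.50 to 2.89, and recovered totals ran from 78532 to 455250 counts per sample. Samples with fewer counts give coarser values for weakly expressed genes.

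Groups and replicate numbers were taken from the labels: 5 groups of 3 tumors, all at day 7. The sample titles place 1 sample of each group on each of 3 cartridges, in lanes 8 to 12, with each group always in the same lane, so lane and group cannot be told apart. Cartridge 3, with 1 sample of each group, was run on another day than the other cartridges. Samples from day 14 and the group letter B are not in the table and were not used here. Replicate numbers equal cartridges and are not stated to be matched animals. After removing group means, samples of the same cartridge had a mean correlation of -0.03 (30 pairs, 8 above 0.1, range -0.40 to 0.40) and other pairs 0.016, so the samples were treated as unpaired and the cartridge as a block was kept as an alternative.

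The design called for a log transform only if the values were linear, and since they were already log2 they were used as deposited. Genes with a normalized count of at least 20 in at least 3 samples were tested, which kept 569 and left out 56. All 15 samples entered 1 linear model with a mean per group (limma 3.58.1, lmFit and eBayes, R 4.3.3), from which 11 contrasts were drawn, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Gene lists were tested with fry when at least 3 members were tested, 25 of 28 lists, with camera and an estimated correlation as an alternative. Camera compares a list with the other genes of a panel targeted at immune genes, so it asks another question than fry. The CD8 coreceptor, cGAS-STING and mitochondrial lists had fewer members and were not tested as lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Of the 625 symbols, 616 were found in the RefSeq gene table. Cxcl10, Cdkn1a, Mdm2, Mki67 and Isg15, which had been fixed for naming, are not on the panel table and were not analysed here.

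The groups, contrasts, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule named, per contrast, the 12 called genes with the largest rise and the 12 with the largest fall, or, where fewer than 10 passed, the 5 with the smallest p in each direction as values, together with a set of genes fixed for every contrast and up to 2 examples per list and direction. Alternatives were no filter, 20 added before the logarithm, quantile normalization, centring each sample on its median, eBayes with trend and robust, the cartridge as a block, only the groups of a contrast, each sample left out in turn, and for lists also fry with the block and on centred values. Added after the data were seen were voom weights on the recovered counts, a minimum mean recovered count of 50, the 3 samples whose value of 1 count exceeded 2 left out, and fry on quantile-normalized values. DESeq2 was planned for whole counts and was not run, since the deposited unit is log2.

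The test was checked on simulated log2 values for the 569 genes. They were drawn independently for each gene from a normal distribution with its mean over all samples and its pooled spread within groups. Known rises and falls in equal number were added to the OVA vaccine and RPT group. Real genes are correlated, their spread differs between groups, and most changes had the same direction, all of which this simulation leaves out. Of 100 genes changed by 1 log2 unit 59% were recovered, and of 100 changed by 2 units 91%. Of 156 calls 6 were false (3.85%), and limma made 0 calls with no change added. A raised list was recovered with an adjusted p of 0.00355, and 0 of 23 other lists were called.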

Results

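Total RNA from 15 mouse E.G7-OVA tumors was measured with an nCounter panel of immune exhaustion genes, which counts fluorescent barcodes hybridized to each transcript. E.G7-OVA is a T lymphoma line, derived from EL4 cells, that expresses the model antigen ovalbumin (OVA), so the tumor cells themselves carry many T cell transcripts. The tumors formed 5 groups of 3: untreated; OT-I T cells with empty vector; OT-I T cells with empty vector and radiopharmaceutical therapy (RPT); OT-I T cells with OVA vaccine; and OT-I T cells with OVA vaccine and RPT. OT-I cells are CD8+ T cells whose receptor recognizes an OVA peptide, and they were transferred naive on day -3. The plasmid DNA, either empty or encoding OVA, followed on day -2. RPT was 1.85 MBq of the yttrium-90 labelled agent 90Y-NM600 on day 0, with 5 Gy delivered to the tumor. All 15 tumors were collected 7 days after RPT or at the matching day. The counts recovered from the table summed to between 78532 (OVA vaccine, replicate 3) and 455250 (empty vector and RPT, replicate 2) per tumor. The labels do not say outright that the samples of a group are separate mice, so the p-values measure only the spread between samples.

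The median of the tested genes differed between groups, which bears on every direction given below. It was 6.89 ± 0.24 log2 units (SD, n = 3) in untreated tumors, 6.81 ± 0.20 with empty vector, 7.13 ± 0.28 with empty vector and RPT, 6.77 ± 0.16 with OVA vaccine and 7.69 ± 0.45 with OVA vaccine and RPT. Within plasmid, the sample medians were higher by 0.62 log2 with RPT (2-sided exact permutation test, p = 0.01, where 0.005 was the smallest p the 400 permutations allowed). Changes are therefore given on the deposited scale, with counts of genes and lists and values of some genes also after centring each sample on its median or after quantile normalization. Of 768 results for named genes, 40 kept their direction and lost their call after centring, and 63 did so after quantile normalization. Many of the 768 had no call to lose, since several contrasts called no gene. Among all called genes, 112 of 262 stayed called after centring for RPT after OVA vaccine. For RPT averaged over both plasmids, 127 of 227 did.

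**Figure D1:**
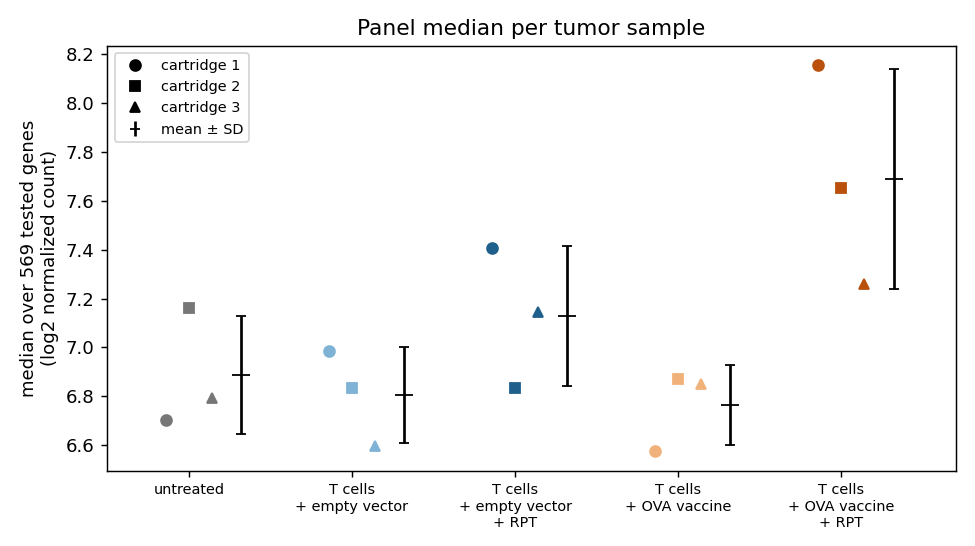
Median log2 normalized count over the 569 tested genes in each tumor, by group, with group mean and SD (n = 3). The group means ran from 6.77 with OVA vaccine to 7.69 with OVA vaccine and RPT.

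The OVA-encoding plasmid was compared with the empty one in tumors without RPT, to ask how vaccination alone changed the RNA of the whole tumor. No gene of the panel passed the test. The smallest p belonged to the kinase gene Prkcz, with a log2 difference of -0.76 (SE 0.26), and other negative differences were -0.83 (SE 0.29) for Il17a, -0.88 (SE 0.33) for Il1b and -1.01 (SE 0.40) for Mmp9. The positive differences with the smallest p included Ifng, the cytokine interferon-gamma, at 4.30 ± 0.38 log2 units with empty vector and 5.04 ± 0.40 with OVA vaccine (SD, n = 3). The granzyme gene Gzmd had a log2 difference of 1.87 (SE 0.72). Among the genes fixed beforehand, Gzmb, a granzyme of killer lymphocytes, and Cd8b1, a chain of the CD8 coreceptor, each had a log2 difference of 1.41, with SE 0.68 and 0.74. Both gave few recovered counts. Gzmb had 4 to 23 with empty vector and 13 to 14 with OVA vaccine, and Cd8b1 had 7 to 38 and 11 to 39. Perforin, encoded by Prf1, had a log2 difference of -0.27 (SE 0.53). By limma, 0 of 569 genes passed, 10 had an unadjusted p under 0.05, the smallest adjusted p was 0.997, and limma with voom weights also called 0. None of the 25 gene lists passed (smallest fry adjusted p 0.969), and the panel median change was -0.01.

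RPT was next compared with no RPT in the mice given T cells and empty vector. Genes of killer lymphocytes were among those with the smallest p, although none passed on the deposited scale. The chemokine gene Ccl5 was at 6.44 ± 0.60 log2 units without and 8.36 ± 0.76 with RPT (SD, n = 3), a log2 difference of 1.92 (SE 0.40) with the same sign in all 3 cartridges and an adjusted limma p of 0.2. Log2 differences were 1.81 (SE 0.44) for Nkg7, a granule membrane protein of killer cells, 2.12 (SE 0.55) for Klrd1, the CD94 receptor, and 1.46 (SE 0.33) for Cd38, an ectoenzyme of activated lymphocytes. The cyclin gene Ccnb1 had a log2 difference of -0.38 (SE 0.15). In limma, 0 of 569 genes passed, against 71 with an unadjusted p under 0.05, and voom weights also gave 0. After median centring 3 genes rose, Ccl5, Cd38 and Nkg7, all with adjusted p 0.0302. Without replicate 2 of the empty vector and RPT group, 1 gene rose on the deposited scale.

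Of the 25 lists in this comparison, none passed fry, which tests whether the members of a list move on balance in one direction and does not compare them with other genes. The cytotoxic effector list had the smallest p: 0 of 14 tested members passed over all genes, 8 rose when adjusted over the list alone, the median change was 1.34 and the fry adjusted p was 0.11. The same list rose after median centring (adjusted p = 0.00491) and after quantile normalization (0.018), with adjusted p = 0.443 with an estimated correlation. Values with an estimated correlation, here and below, are from camera, which compares a list with the other panel genes. Over the whole panel the median change was 0.20.

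After the OVA vaccine, RPT was accompanied by a rise of many immune transcripts on the deposited scale. Perforin (Prf1) rose 10.6-fold, from 4.43 ± 0.09 to 7.83 ± 1.37 log2 units (SD, n = 3), and Klrd1 rose 10.7-fold. Both folds are imprecise, since the tumors without RPT gave 7 to 34 recovered counts of Prf1 and 8 to 106 of Klrd1. Ctla4, an inhibitory receptor of activated and regulatory T cells, rose from 1 to 8 recovered counts per tumor to 24 to 33, too few for a precise fold, and the interferon-induced Ifit3/3b rose 8.31-fold. Decorin (Dcn), a matrix protein of fibroblasts, rose 8.28-fold, from 6.61 ± 0.50 to 9.66 ± 1.18. The transcription factor gene Tox, linked with T cell exhaustion, fell by 0.92 on the log2 scale, and cyclin B1 (Ccnb1) fell by 0.56. Tox was as high in untreated tumors, which received no T cells, as with OVA vaccine. Limma called 262 of 569 genes, of which 250 rose and 12 fell.

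Other genes with large rises in this comparison were Aldh1a1 (log2 change 3.58), Zbtb16 (3.47), Cd6 (3.15), Egfr (3.03), Nkg7 (2.96) and Nfatc4 (2.96). Several of these were near the lower end of the assay without RPT: Ctla4 stood at 1.80 log2 units, Aldh1a1 at 2.33 and Cd6 at 2.68. The other genes that fell were Mapk10 (-1.14), the ubiquitin ligase gene Hecw2 (-0.99), Rasgrp1 (-0.85), which couples the T cell receptor to Ras, the checkpoint kinase gene Chek1 (-0.71), Psma6 (-0.63), Rac1 (-0.57), Dld (-0.56), Ppp2r1a (-0.53), Nup54 (-0.53) and Hadhb (-0.41). Hadhb no longer passed with the cartridge as a block (limma adjusted p = 0.0619).

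The panel median change here was 0.75 log2, so the balance of directions depended on scaling. After median centring 100 genes rose and 165 fell, and after quantile normalization 82 rose and 113 fell. Of the genes called on the deposited scale, 100 of the 250 that rose and all 12 that fell were also called after centring with the same sign, and 0 were called with opposite signs by limma. Centring lowered every change here by the same amount. A gene that fell could therefore only fall further, and one that rose after centring had to rise before it. Of the 262 genes, 251 had the same sign in all 3 cartridges. Leaving out replicate 1 of the OVA vaccine and RPT group gave 142 genes, leaving out replicate 1 of the OVA vaccine group gave 145, leaving out the 3 samples whose counts were scaled up most gave 140, and fitting the 6 samples of this comparison alone gave 155.

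Genes of killer lymphocytes rose together. Of 14 tested cytotoxic effector genes, 12 rose and 0 fell by limma, 13 rose when adjusted over the list alone, and the median log2 change was 2.07 (fry adjusted p = 0.00204). After centring, 8 rose and 0 fell by limma. Gzmb rose from 4.04 ± 1.17 to 6.18 ± 1.04 log2 units (limma adjusted p = 0.0233). It gave only 13 to 14 recovered counts in the OVA vaccine tumors, so the spread of its values there came mostly from the scale factors. With RPT it gave 25 to 99. Ifng rose by 1.11 (SE 0.26), although the Ifng change was -0.34 after quantile normalization. Gzma, another granzyme gene, did not pass (0.68, SE 0.30, adjusted p = 0.0754). The CD8 coreceptor genes Cd8a and Cd8b1 rose from 3.60 ± 0.53 to 5.37 ± 0.83 and from 4.69 ± 0.27 to 6.70 ± 0.72. After centring, Gzmb, Cd8a and Cd8b1 no longer passed (adjusted p = 0.117, 0.0514 and 0.144). Among 3 natural killer cell markers, 1 rose, Klrd1, and 2 rose when adjusted over the list alone (fry adjusted p = 0.00899), whereas the balance turned downward without passing after quantile normalization (0.993). Klrd1 and Xcl1 of these markers are also on the cytotoxic list, here and below, so only Ncr1 is separate from it. Ncr1, the NKp46 receptor of natural killer cells, had a log2 difference of 0.92 (SE 0.37, adjusted p = 0.0576). The cytotoxic list had adjusted p = 0.788 with an estimated correlation and the natural killer list had adjusted p = 0.806.

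Of 20 tested exhaustion-associated receptors and transcription factors, 13 rose and 1 fell, with the same counts adjusted over the list alone (median 1.57, fry adjusted p = 0.00277). Havcr2, which encodes the inhibitory receptor TIM-3, rose from 4.31 ± 0.34 to 6.96 ± 0.60 log2 units, and Lag3, another inhibitory receptor, rose by 2.40 (SE 0.69). Tox moved the other way, from 8.93 ± 0.20 to 8.01 ± 0.40. It also averaged 8.93 in untreated tumors, which received no T cells, so its fall need not concern the transferred T cells. Pdcd1, the PD-1 gene, did not pass (0.33, SE 0.27), and after centring it fell by 0.59 (adjusted p = 0.0226). Tigit had a log2 difference of 0.63 (SE 0.40, adjusted p = 0.207). Among 11 costimulatory receptors and ligands, 7 rose over all genes and 8 adjusted over the list alone (fry adjusted p = 0.00358). Tnfrsf9, the costimulatory receptor 4-1BB, rose by 2.33 and Icosl, the ligand of ICOS, by 2.13. This list no longer passed after quantile normalization (0.232). Both lists had adjusted p = 0.788 with an estimated correlation.

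Genes that mark all T cells, which the lymphoma also expresses, behaved unlike the cytotoxic list. Of 12 tested, 2 rose, Cd6 and the T cell receptor beta constant probe Trbc1/2, also with 2 adjusted over the list alone, and 10 did not pass. The list median was 0.01, its mean 0.56 and its fry adjusted p = 0.0445 upward, which became 0.0625 with the cartridge as a block, and after centring the list fell (adjusted p = 0.0384). Of 10 stem-like and memory T cell genes 3 rose, also 3 adjusted over the list alone, with Klf2 up by 2.55 and the interleukin-7 receptor gene Il7r by 1.82. That list did not pass (fry adjusted p = 0.05) and fell after quantile normalization (0.0116). Tcf7, the memory factor TCF-1, had a log2 difference of -0.17 (SE 0.19), and after centring it fell by 1.10 (adjusted p = 0.009). Of 5 CD4 and regulatory T cell genes 4 rose, or 5 adjusted over the list alone (median 1.73, fry adjusted p = 0.000766). Foxp3, which defines regulatory T cells, rose by 2.28 (SE 0.77; adjusted p = 0.078 after centring), and Cd4 did not pass (1.11, SE 0.43, adjusted p = 0.0518). The pan-T list and the CD4 and regulatory list had adjusted p = 0.788 with an estimated correlation, and the stem-like list 0.883.

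Interferon-stimulated genes and antigen presentation rose as well. Of 11 type I interferon-stimulated genes 8 rose, or 10 adjusted over the list alone (median 1.93, fry adjusted p = 0.00358), with Oas2, an antiviral RNA sensor, up by 2.62 (SE 0.65). After quantile normalization this list no longer passed (0.0538). Of 10 interferon-gamma response genes 4 rose, or 6 adjusted over the list alone (fry adjusted p = 0.00743), with the GTPase gene Gbp2 up by 2.02 and Cd274, which encodes PD-L1, going from 6.76 ± 0.22 to 8.75 ± 0.43 log2 units. The chemokine gene Cxcl9 had a log2 difference of 0.95 (SE 0.43, adjusted p = 0.085). Of 7 MHC class II genes 6 rose, also 6 adjusted over the list alone (fry adjusted p = 0.0117), H2-Eb1 by 1.99 and H2-Ab1 by 1.95. Of 9 MHC class I genes 5 rose, also 5 adjusted over the list alone (fry adjusted p = 0.0315), with Tapbp, the peptide-loading protein tapasin, up by 2.69 and the nonclassical H2-T23 up by 2.42. Relative to the panel median the last 3 lists no longer passed, with adjusted p = 0.122, 0.122 and 0.987. For MHC class I adjusted p = 0.9 with an estimated correlation, and adjusted p = 0.788 for the others.

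Myeloid markers rose too. Of 11 macrophage and monocyte markers 7 rose, or 10 adjusted over the list alone (median 1.65, fry adjusted p = 0.00277), with Trem2, a lipid-sensing receptor of macrophages, up by 2.90, its adaptor gene Tyrobp up by 2.40 and Cd68 going from 8.94 ± 0.20 to 10.83 ± 0.68 log2 units. Of 16 suppressive myeloid and immunoregulatory genes 8 rose, also 8 adjusted over the list alone (fry adjusted p = 0.00358, or 0.0774 after centring). Cd276, the B7-H3 ligand, rose by 2.50, and arginase 1 (Arg1) went from 7.11 ± 0.60 to 9.12 ± 0.57 (adjusted p = 0.101 after centring). Of 5 neutrophil markers 3 rose, also 3 adjusted over the list alone (fry adjusted p = 0.0097), with Csf3r, the G-CSF receptor, up by 2.66 and Il1r2 up by 1.90. Of 5 dendritic cell markers 4 rose, also 4 adjusted over the list alone (fry adjusted p = 0.0112), among them Itgax by 1.51. Another of the 4 was Cd8a, the CD8 coreceptor gene that T cells also express. After quantile normalization the neutrophil and the dendritic list turned downward without passing (0.326 and 0.691). The neutrophil list had adjusted p = 0.806 with an estimated correlation, and the other three lists had adjusted p = 0.788.

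Of 11 chemokine genes 7 rose, also 7 adjusted over the list alone (median 1.55, fry adjusted p = 0.00411), with the neutrophil attractant Cxcl1 up by 2.48 and Ccl3 up by 2.32. Of 12 inflammasome and NF-kB genes 7 rose, or 10 adjusted over the list alone (fry adjusted p = 0.00266, but 0.748 after centring), with the interleukin-1 receptor gene Il1r1 up by 2.28 and Il18 up by 1.56. Of 5 stromal and endothelial markers 3 rose, also 3 adjusted over the list alone (median 1.80, fry adjusted p = 0.00538), with Pdgfra, a receptor of fibroblasts, up by 2.31 (SE 0.60). Of 4 B cell markers 2 rose, also 2 adjusted over the list alone, Cd22 by 2.05 and Btk by 1.42, and the list did not pass (0.0942; downward and not passed after centring, 0.911). Of 6 TGF-beta pathway genes 1 rose, Ltbp1, and none did when adjusted over the list alone. That list did not pass (0.389), and after centring it fell (0.00275). The B cell list had adjusted p = 0.946 with an estimated correlation, and the other four had adjusted p = 0.788.

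Proliferation genes went the other way. Of 7 cell cycle genes 0 rose and 2 fell by limma, Chek1 by 0.71 (SE 0.21) and Ccnb1 by 0.56 (SE 0.15), also 2 adjusted over the list alone. The list fell on the deposited scale (median -0.29, fry adjusted p = 0.00411), and all 7 members fell after centring and after quantile normalization. Its adjusted p = 0.0955 with an estimated correlation. Of 6 p53 target and DNA damage response genes 3 rose, also 3 adjusted over the list alone (fry adjusted p = 0.0252), with the death receptor gene Tnfrsf10b up by 2.47 and Gadd45a up by 1.26. After quantile normalization that list fell (0.0445). Of 7 lipid metabolism genes 3 rose and 1 fell, or 4 and 1 adjusted over the list alone (fry adjusted p = 0.029), with the adipogenic factor Pparg up by 2.20 and lipoprotein lipase (Lpl) up by 1.89, and the list turned downward without passing after centring (0.0774). Of 4 epigenetic regulators 1 rose, also 1 adjusted over the list alone: the acetyltransferase gene Crebbp, by 0.70, which was -0.22 after centring. That list passed upward (0.0445), not with the cartridge as a block (0.062), and fell after centring (0.0226). None of 3 glycolysis genes passed limma, with 0 adjusted over the list alone, as for Aldoa (0.70, SE 0.28, unadjusted p = 0.0265), and the list (0.364) fell after centring (0.00424). With an estimated correlation, adjusted p = 0.883 for p53 targets, 0.946 for lipid metabolism, 0.858 for epigenetic regulators and 0.788 for glycolysis.

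In all, 21 of 25 lists passed fry after OVA vaccine, 20 upward and 1 downward. After centring 13 passed, 8 upward and 5 downward, and after quantile normalization 11 passed, 7 upward and 4 downward. The cytotoxic, exhaustion, macrophage, CD4 and regulatory T cell, stromal and chemokine lists passed upward, and the cell cycle list downward, on all 3 scales. Some of these lists share genes, so they are not separate results. Ccl3, Ccl4 and Ccl5 rose on both the chemokine and the cytotoxic list. Ctla4 rose on both the exhaustion list and the CD4 and regulatory T cell list. With an estimated correlation 0 lists passed camera, against 21 by fry.

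**Figure D2:**
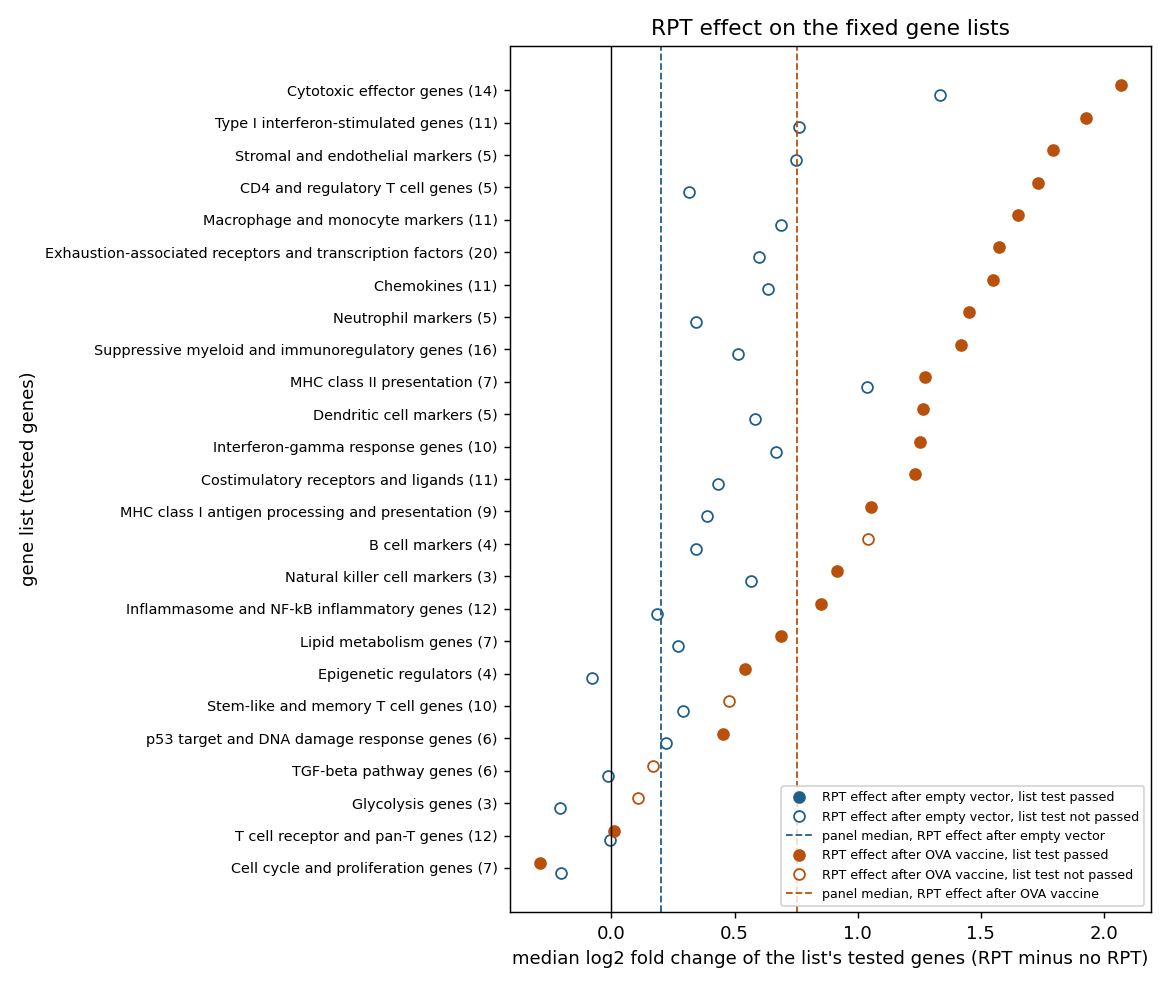
Median log2 change with RPT of each tested list after empty vector and after OVA vaccine, filled where the list passed fry, with dashed lines at the panel medians of 0.20 and 0.75. The cytotoxic list stood at 1.34 and 2.07 and the cell cycle list at -0.20 and -0.29. On quantile-normalized values the medians after OVA vaccine turned negative for the pan-T (-0.23), stem-like (-0.63), TGF-beta (-0.75), neutrophil (-0.07), natural killer (-0.53), B cell (-0.22), p53 (-0.48), glycolysis (-0.26), epigenetic (-0.22) and inflammasome (-0.08) lists, and after median centring that for lipid metabolism did (-0.23).

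The OVA vaccine was compared with the empty vector among tumors that all received RPT, to ask what the vaccine added to RPT. No gene passed. Cd14, a monocyte receptor gene, was at 5.53 ± 0.25 log2 units with empty vector and RPT and at 6.75 ± 0.60 with OVA vaccine and RPT (SD, n = 3). Log2 differences were 1.66 (SE 0.39) for Havcr2, 1.59 (SE 0.38) for Prdm1, the effector factor Blimp-1, and 1.99 (SE 0.48) for Trem2, each with adjusted limma p 0.11 and the same sign in all 3 cartridges. Prf1 and Gzmb had differences of 1.94 (SE 0.53) and 2.17 (SE 0.68), and Tox one of -0.62 (SE 0.21). The CD4 and regulatory T cell list passed: 0 of 5 members passed over all genes, 3 rose when adjusted over the list alone, and the median was 1.07 (fry adjusted p = 0.0309). It no longer passed after centring (0.0998) or quantile normalization (0.0986), and had adjusted p = 0.923 with an estimated correlation.

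By limma, 0 of 569 genes passed in this comparison, 169 had an unadjusted p under 0.05, voom weights gave 0, and after quantile normalization 1 gene fell and 0 rose. Without replicate 3 of the OVA vaccine and RPT group, 146 genes passed, so this 1 sample decided the count. Over all tested genes the median change was 0.50, against -0.06 after centring.

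Whether the effect of RPT differed between OVA vaccine and empty vector was tested by the interaction. No gene passed. Prdm1 had the smallest p, with an interaction of 2.59 log2 (SE 0.53, limma adjusted p = 0.202), followed by Cd14 with 1.51 (SE 0.37), and the interaction for Ctla4 was 2.61 (SE 0.68). Ctla4 gave few recovered counts, 1 to 8 with OVA vaccine, and Gzmb gave 13 to 14 there. The values for Prf1, Gzmb and Cd8b1 were 2.21 (SE 0.75), 0.76 (SE 0.97) and -0.20 (SE 1.04); that for Gzmb was -0.10 after quantile normalization. In limma, 0 of 569 genes passed, 69 had an unadjusted p under 0.05, voom weights gave 0, and leaving out replicate 3 of the OVA vaccine and RPT group gave 1. The CD4 and regulatory T cell list came closest among the lists (fry adjusted p = 0.0549) and passed with the cartridge as a block (0.0328), with adjusted p = 0.663 with an estimated correlation. The panel median of the interaction was 0.47.

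Both RPT effects, which share no samples, can also be set side by side. Across the 569 genes, which are not independent replicates, they had a Pearson r of 0.753 and a Spearman rho of 0.766. Of the 250 genes that rose after OVA vaccine, 235 (94%) had a positive change after empty vector, as did 74.7% of all genes tested, and all 12 that fell had a negative one, as did 25.3%. After median centring, 96 of the 100 genes that rose had a positive change after empty vector (40.8% of all genes), and 162 of the 165 that fell had a negative one (59.2%).

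Averaged over both plasmids, RPT raised 217 genes and lowered 10 of 569 by limma. The largest rises were in Zbtb16 (3.04, SE 0.70), Aqp7 (2.85, SE 0.96, same sign in 2 of 3 cartridges), Klrd1 (2.77, SE 0.39), Ghr (2.63), Aldh1a1 (2.43) and Nkg7 (2.39, SE 0.31). The adipocyte fatty acid binding protein gene Fabp4 rose by 2.34, and Lpl by 1.78. Prf1 rose by 2.29 (SE 0.37), Ctla4 by 2.26 (from few recovered counts), Dcn by 2.22, Egfr by 2.19 and Klrc1, which encodes the CD94 partner NKG2A, by 2.18. The genes that fell were Mapk10 (-0.79), Tox (-0.59), Rasgrp1 (-0.56), Ccnb1 (-0.47), Chek1 (-0.45), Ptpn6 (-0.36), Dld, Rac1, Psma6 and Nup54. With the cartridge as a block, Rac1 and Psma6 no longer passed (limma adjusted p = 0.0682 and 0.0674).

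Of the 25 lists, 19 rose and 1 fell by fry with the averaged RPT effect, and 0 passed camera with an estimated correlation. Of 14 cytotoxic genes 12 rose, or 13 adjusted over the list alone (median 1.78, fry adjusted p = 0.00121). Of 11 type I interferon-stimulated genes 9 rose, or 10 adjusted over the list alone (0.00318), and of 11 macrophage markers 7 rose, or 9 adjusted over the list alone (0.00318). The list that fell was the cell cycle list, with 2 of 7 members called and 3 adjusted over the list alone (0.00318). With an estimated correlation, adjusted p = 0.675 for the first 3 and 0.0507 for the cell cycle list. The panel median change was 0.45, and 117 genes rose and 168 fell after centring, 79 and 109 after quantile normalization. With a minimum mean recovered count of 50, fewer genes entered and 145 were called; 13 lists passed after quantile normalization.

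The vaccine effect averaged over RPT and no RPT left no gene past the test. Ifng had the smallest p, with a log2 difference of 0.84 (SE 0.18, limma adjusted p = 0.343) and the same sign in all 3 cartridges. Gzmb had a log2 difference of 1.79 (SE 0.48), the interferon-induced Ifit1 one of 1.09 (SE 0.27) and the chemokine receptor gene Ccr1 one of 0.67 (SE 0.17). Without RPT, Gzmb gave few recovered counts, 4 to 23 with empty vector and 13 to 14 with OVA vaccine. By limma, 0 of 569 genes passed, 62 had an unadjusted p under 0.05, voom weights gave 0, and 0 lists passed. Without replicate 1 or replicate 2 of the empty vector and RPT group, 2 and 1 genes passed. Over the panel the median change was 0.22.

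Against untreated tumors, the full combination of T cells, OVA vaccine and RPT was accompanied by a rise of cytotoxic genes. Klrc1 rose 26-fold, from 3.23 ± 0.75 to 7.93 ± 0.73 log2 units (SD, n = 3), Klrd1 20-fold and Prf1 18.3-fold. Havcr2 rose 16.9-fold, from 2.88 ± 0.74 to 6.96 ± 0.60, Cd8b1 11.8-fold and Gzmb 11.6-fold. These folds are imprecise, since the untreated tumors gave few recovered counts: 5 to 12 for Klrc1, 7 to 16 for Prf1, 2 to 13 for Havcr2, 4 to 14 for Cd8b1 and 3 to 8 for Gzmb, with the background of the assay unknown. Nkg7 (3.46), Trem2 (3.24), Zbtb16 (3.21), Lag3 (3.19), Ifit3/3b (3.16) and Gbp2 (3.03) followed. The genes with the largest falls were Hecw2 (-1.34), the immunoglobulin mu chain gene Ighm (-0.97), Tox (-0.92), Ccnb1 (-0.76), the T helper factor gene Gata3 (-0.73), Rasgrp1 (-0.72) and the phosphatase gene Ptpn6 (-0.71). Ighm no longer passed with the cartridge as a block (limma adjusted p = 0.057). Limma called 216 genes, 201 up and 15 down.

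All 14 cytotoxic effector genes rose in this comparison, also 14 adjusted over the list alone (median 2.83, fry adjusted p = 0.000161). All 11 type I interferon-stimulated genes rose, also 11 adjusted over the list alone (median 1.80, 0.00178), and after centring 8 of them still passed. Of 10 interferon-gamma response genes 7 rose, or 9 adjusted over the list alone (0.00136), with Cxcl9 at 6.74 ± 0.32 in untreated and 9.78 ± 0.67 log2 units in treated tumors. Of 7 MHC class II genes 6 rose, also 6 adjusted over the list alone (0.00257), with H2-Ab1 up by 2.69. Of 11 chemokines 9 rose, or 10 adjusted over the list alone (0.000996), and of 11 macrophage markers 7 rose, also 7 adjusted over the list alone (0.00312). Of 7 cell cycle genes 2 fell, Ccnb1 and E2f2, also 2 adjusted over the list alone (0.000996). With an estimated correlation, adjusted p = 0.636 for the cytotoxic list, 0.637 for the interferon, MHC class II and chemokine lists, 0.691 for macrophages and 0.143 for the cell cycle.

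In all, 17 of 25 lists passed fry for the full combination, 16 upward and 1 downward, and 0 passed camera with an estimated correlation. The panel median change was 0.61. After centring, 126 genes rose and 190 fell, and after quantile normalization 83 rose and 124 fell. Without replicate 1 of the OVA vaccine and RPT group 126 genes were called, without replicate 1 of the untreated group 138, with a minimum mean recovered count of 50 the number was 142, and with these 6 samples alone it was 119.

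T cells with empty vector and RPT raised 20 genes and lowered 0 of 569 against untreated tumors by limma, with 97 at an unadjusted p under 0.05. Klrc1 rose 10.5-fold, from 3.23 ± 0.75 to 6.62 ± 0.64 log2 units, Klrd1 8.46-fold and Havcr2 5.35-fold, again from as few as 5 recovered counts of Klrc1 and 2 of Havcr2 in an untreated tumor. Cxcl9 rose from 6.74 ± 0.32 to 9.18 ± 0.77, and Gbp2 (2.26), Prf1 (2.26), Nkg7 (2.12), the chemokine gene Xcl1 (2.11), Ccl5 (2.08), Lpl (1.98), the activating receptor gene Klrk1 (1.93) and the Fc receptor gene Fcgr4 (1.80) also rose. Of 14 cytotoxic genes 8 rose, or 11 adjusted over the list alone (median 1.75, fry adjusted p = 0.0114), and of 3 natural killer markers 2 rose, also 2 adjusted over the list alone (0.0268). Those 2, Klrd1 and Xcl1, are also among the 8 cytotoxic genes. The cell cycle list fell (median -0.24, 0.0268) with 0 of 7 members called by limma and 2 adjusted over the list alone, and no longer passed after centring (0.0839) or quantile normalization (0.141). With an estimated correlation, adjusted p = 0.27 for the cytotoxic and cell cycle lists and adjusted p = 0.46 for the natural killer list.

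The number of genes in that comparison was less stable than in the full combination. It was 5 with the cartridge as a block, 8 without the filter, 7 with 20 added before the logarithm, 13 without the 3 samples scaled up most, 0 with voom weights and 0 with the 6 samples alone. Without replicate 1 of the empty vector and RPT group 1 gene was called, without replicate 3 of that group 3, and without untreated replicates 1, 2 and 3 there were 3, 2 and 3. The panel median change was 0.10, and 10 lists passed after centring against 3 on the deposited scale.

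T cells with OVA vaccine but no RPT lowered 1 gene against untreated tumors, Il17a, which encodes interleukin-17A. It fell by 1.82 on the log2 scale (SE 0.29, limma adjusted p = 0.0229), from 4.41 ± 0.28 to 2.60 ± 0.48 log2 units (SD, n = 3), in all 3 cartridges. Il17a lay near the floor of the assay, with 13 to 27 recovered counts in untreated and 3 to 7 in OVA vaccine tumors. A minimum mean recovered count of 50 left Il17a itself out, and limma then called 0 genes. Log2 differences that did not pass were 2.08 (SE 0.43) for Cxcl9, 1.93 (SE 0.45) for Xcl1, 2.07 (SE 0.49) for Klrc1 and -2.21 (SE 0.64) for the regulatory cytokine gene Il10. After centring, 3 genes rose, as they did after quantile normalization, with adjusted p after centring of 0.00582 for Cxcl9, 0.0165 for Xcl1 and 0.00784 for Klrc1. By limma, 0 genes rose and 29 genes had an unadjusted p under 0.05. The Il17a call was lost with the cartridge as a block (adjusted p = 0.0664), with voom weights and when any of 5 samples was left out, namely each untreated tumor and OVA vaccine replicates 1 and 2, each of which gave 0 genes. None of the 25 lists passed on the deposited scale. The cytotoxic and natural killer lists, which share Klrd1 and Xcl1, rose after centring (fry adjusted p = 0.00294 and 0.0079), with adjusted p = 0.18 with an estimated correlation for both. The median change over the panel was -0.13.

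T cells with empty vector and no RPT did not differ detectably from untreated tumors in any gene. The smallest p belonged to Il10, with a log2 difference of -2.29 (SE 0.64), and to Xcl1 and Klrc1, with 1.55 (SE 0.45) and 1.66 (SE 0.49), all with adjusted limma p 0.762. Havcr2 and Cxcl9 had log2 differences of 1.26 (SE 0.39) and 1.20 (SE 0.43). By limma, 0 of 569 genes passed, 10 had an unadjusted p under 0.05 and voom weights gave 0. None of the 25 lists passed on the deposited scale, and 1 of them, the natural killer list, rose after centring (adjusted p = 0.035), with adjusted p = 0.0615 with an estimated correlation. The median change over the panel was -0.09.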

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

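The voom weights, the minimum mean recovered count of 50, leaving out the 3 samples scaled up most and the list tests on quantile-normalized values were chosen only after the data were seen. Of 13339 alternative values for 768 named gene results, 12361 kept direction and side of the threshold, but many of these results were not called in the reported setting. With the replicate block 744 of 768 did, 22 lost their call and 2 gained one. Gene counts within 1.5 times are not repeated. For RPT after empty vector, centring gave 3 genes against 0 by limma, and leaving out single samples gave 0 to 1. For RPT after OVA vaccine (262), leaving out the 3 samples gave 140 and the 2 groups alone 155, and single samples left out gave 142 to 322. Fewer samples enter these fits. The groups-alone fit also uses another spread, since the main model shares 1 spread per gene over all groups. The SD of the sample medians was 0.45 with OVA vaccine and RPT and 0.16 with OVA vaccine. Which of these lowered this and the other groups-alone counts was not tested. For the vaccine effect with RPT (0), quantile normalization gave 1 and single samples left out 0 to 146. The same ranges were 0 to 1 for the interaction and 0 to 2 for the average vaccine effect. For the average RPT effect (227), the minimum count gave 145, with fewer genes tested. For empty vector and RPT against untreated (20), no filter gave 8, adding 20 gave 7, the replicate block 5, voom weights 0, the 3 samples left out 13 and the groups alone 0, with 1 to 28 over single samples. For OVA vaccine against untreated (1), adding 20, trend and robust, the replicate block, voom weights, the minimum count and the groups alone each gave 0, quantile normalization and centring each gave 4, and single samples left out gave 0 to 1. The minimum count left the 1 called gene, Il17a, out of the test. For OVA vaccine and RPT against untreated (216), the minimum count gave 142, the groups alone 119, and single samples left out 126 to 275. For lists, camera with an estimated correlation, which compares a list with the other panel genes, gave 0 in each comparison where fry had passed any. Centring gave 1 list for RPT after empty vector, 13 for RPT after OVA vaccine, 0 for the vaccine effect with RPT, 1 for empty vector, 10 for empty vector and RPT and 2 for OVA vaccine against untreated; quantile normalization gave 1, 11, 0, 1, 6 and 2 in the same order and 13 for the average RPT effect. The replicate block gave 1 list for the interaction. Named changes that were called in the reported or the alternative setting and turned in sign did so under rescaling, whose construction removes a panel-wide shift (turns of values called in neither setting are not listed): for RPT after OVA vaccine, Ifng -0.34 after quantile normalization, and Pdcd1 -0.59 and Crebbp -0.22 after centring; for the average RPT effect, Ifng -0.033, Ncr1 -0.80, Fas -0.14 and Il18 -0.11 after quantile normalization and Pdcd1 -0.47 after centring; for OVA vaccine and RPT against untreated, Ncr1 -0.14, Tnfrsf10b -0.19 and Fas -0.19 after quantile normalization and Pdcd1 -0.70, Crebbp -0.56 and Dnmt3a -0.74 after centring. For the other changes the cause was not tested. DESeq2 was planned and not run. Depth limited mostly the weakly expressed genes: the shallowest sample, OVA vaccine replicate 3, had 255 genes under 20 counts.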

Other observations

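Several further gene lists, some of which share members with those described so far, rose between untreated tumors and the full combination. Of 20 exhaustion-associated genes 11 rose and 1 fell, or 13 and 1 adjusted over the list alone (fry adjusted p = 0.00312), with Ctla4 up by 2.98 log2 (SE 0.48) and Tox down, from 8.93 ± 0.14 to 8.01 ± 0.40 (SD, n = 3). The Ctla4 change is imprecise, since untreated tumors gave 3 to 9 recovered counts of it. All 3 natural killer markers rose, also 3 adjusted over the list alone (0.000461). Klrd1 and Xcl1 of these are also on the cytotoxic list, and Ncr1, which is not, was -0.14 after quantile normalization. Of 16 suppressive myeloid genes 8 rose, also 8 adjusted over the list alone (0.00374), among them Nos2, the inducible nitric oxide synthase, by 2.51 (SE 0.54). Of 5 stromal markers 3 rose, or 5 adjusted over the list alone (0.00568), with Dcn up by 2.85 and Pdgfra by 1.81. Each of these lists also passed after centring and after quantile normalization, with adjusted p = 0.709 with an estimated correlation for exhaustion and suppressive myeloid genes, 0.637 for natural killer markers and 0.691 for stromal markers. Of 7 lipid metabolism genes 2 rose, also 2 adjusted over the list alone, Pparg by 2.69 and Lpl by 2.40, and the list did not pass (0.0591; downward and not passed after centring, 0.102).

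All tests of the next paragraphs were chosen only after the result was seen, except that on the better counted genes and the counts over other splits of the samples. The rise of most panel genes in the OVA vaccine and RPT tumors over the OVA vaccine tumors was first set against 1 scale factor per sample as the whole cause, which would move all lists alike, but the cytotoxic list rose 1.43 log2 more than the pan-T list (SE 0.28). Low counts scaled up in shallow samples would leave well-counted genes without a shift, yet the 285 genes above the middle of the mean counts had a median change of 0.31 (0.57, 0.21 and 0.15 in the 3 cartridges), so it was argued against for these genes. The other 284 genes had a larger median change of 1.37. Their normalized values differed by 1.26 log2 (SE 0.29). The value of 1 count made up 0.23 (SE 0.60) of this and the recovered counts 1.03 (SE 0.48), which did not pass. Scaling of low counts therefore stays open for these 284 genes. Their median changes were 2.14, 1.45 and 0.39 in the 3 cartridges. In the same order, the value of 1 count with and without RPT was 2.33 and 0.64, 1.30 and 0.95, and 0.93 and 2.89. The change was thus largest where the RPT sample was scaled up most against the other, and smallest, though positive, where it was scaled up less. The changes of the 285 better counted genes had the same order across the cartridges. A lower share of lymphoma cells may also contribute and stays open, since it would raise every other cell type alike and the smallest adjusted p among the 10 pairs of cell type lists was 0.087. The zero point of the authors' normalization and the lane, which is the same for all samples of a group, cannot be separated from treatment, and the treatment itself remains among the open explanations.

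The second pattern was the rise of the cytotoxic list in the same comparison. One scale factor per sample as the whole cause was argued against by a centred change of 1.06 log2 (SE 0.17). More CD8 T cells of unaltered makeup would raise Cd8a and Cd8b1 as much as the list, and the list changed 0.096 log2 more than they did (SE 0.41). More natural killer cells would raise Ncr1 as much as the list, and the list rose 1.06 log2 more than Ncr1 (SE 0.37). Both hypotheses stay open, since which cells carried the transcripts was not measured. Cd8a and Ncr1 also lay near the floor of the assay, with means of 17.6 and 13 recovered counts. Cd8b1 was counted better, with a mean of 39.2. It gave 11 to 39 counts in the OVA vaccine tumors and 68 to 78 in the OVA vaccine and RPT tumors. Scaling of low counts stays open for part of the rise too. The cytotoxic list averaged 4.96, 5.21 and 5.37 log2 units in the 3 OVA vaccine tumors. The 284 less well counted genes had medians of 4.57, 4.93 and 5.11 in the same tumors.

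Other splits of the samples were counted for each comparison. For the average RPT effect, 2 of 100 splits gave as many genes as the real 227. The other gave 239 and differed from the real one only by exchanging the empty vector pair of cartridge 2. The share was below the 0.05 fixed beforehand, which argues against chance for this count without excluding it. These splits cannot tell treatment from lane. For the interaction and the average vaccine effect, the real count by limma was 0, which all 100 of 100 splits reach by construction, so the splits say nothing about chance there. The highest others were 241 and 70, and what gave these counts was not tested. For comparisons of 3 against 3, the 10 splits are too few for a share under 0.05. The real count and the highest other were 262 and 0 for RPT after OVA vaccine (1 split as large, the real one), 216 and 8 for the full combination against untreated (1), 20 and 0 for empty vector and RPT against untreated (1), and 1 and 0 for OVA vaccine against untreated (1). They were 0 and 81 for the vaccine effect with RPT, where the split with 81 exchanges OVA vaccine and RPT replicate 3 with empty vector and RPT replicate 1 and points to a structure among these samples. They were 0 and 0 by limma for the vaccine effect without RPT, for RPT after empty vector and for empty vector against untreated, where a real 0, as in the vaccine effect with RPT, is reached by all 10 splits by construction.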
